A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

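Newly made RNA of budding yeast (Saccharomyces cerevisiae) was measured on 16 dual-colour expression arrays, in 2 strains at 4 times, with 2 arrays in each of the 8 groups. Mot1-aa is an anchor-away strain: Mot1, an ATPase that removes the TATA-binding protein from DNA, carries an FRB domain together with GFP and V5 tags, and the ribosomal protein Rpl13A carries FKBP12. Rapamycin joins both domains, so that the tagged protein is carried out of the nucleus with new ribosomal subunits. WT-aa is the parental strain, which has the FKBP12 anchor but no FRB tag. Both strains carry the tor1-1 allele and lack FPR1, which together make growth insensitive to rapamycin. Per the labels, cells grew in synthetic complete medium with 2% glucose, received 7.5 µM rapamycin for 0, 10, 20 or 30 min, and were given 5 mM 4-thiouracil (4tU), a uracil analogue that enters new RNA, for the last 6 min before harvest. The RNA that had taken up 4tU was coupled to biotin, captured on streptavidin beads, amplified, and hybridised against a common reference, which was 4tU-labelled RNA pooled from several WT-aa cultures without rapamycin. Per the labels, each group was grown as 2 independent cultures, called culture 1 and culture 2 here, and the dyes were exchanged between them: the sample was Cy3 in culture 1 and Cy5 in culture 2. Whether the 4 times of a strain were taken from the same culture is not given in the sources used here.

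The deposited scanner tables hold intensity values: per the file headers, the mean and median brightness of each spot and of its local background in each channel, on a linear scale and without background subtraction. The authors' series table holds a normalized log2 ratio of Cy5 over Cy3 per spot, and how the authors normalized it is not given in the sources used here. The scanner and the quantification software are likewise not given in the sources used here. The scanner values were the starting point of every comparison, and the authors' log2 ratios, turned to sample over reference, served as an alternative. Their medians per array lay between -0.002 and 0.015, and they followed the ratios computed from the scanner values with r between 0.796 and 0.978 across the spots of an array. The dye labels were checked on the values. The channel labelled as the reference was the more alike one across arrays in both orientations, with a mean r of 0.993 in Cy5 against 0.979 in Cy3 for culture 1, and of 0.997 in Cy3 against 0.985 in Cy5 for culture 2.

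Each array carried 15552 spots, of which 12776 were gene spots (6388 probes in duplicate), 1872 were external control spots and 904 were quality control spots. A gene name was given for 5326 probes; 1062 probes had none and were left out of the comparisons. Names were matched to the R64 gene table, which gave 5255 current symbols and 54 symbols through a synonym, while 6 names were kept as the platform gave them. The mean of both probes was used for the 11 genes with 2 probes, which left 5315 genes. The deposited tables name no genome build, so genes are identified by symbol and locus tag without coordinates. Processing used limma 3.58.1 in R 4.3.3: normexp background correction with an offset of 50, loess normalization within each array over the gene spots, log2(sample/reference), and the mean of duplicate spots. Loess sets the typical gene of every array to a log2 ratio of 0, so every change below is relative to the other genes of the same arrays.

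Depth on an array is the signal over the background. The median sample signal ranged from 406.7 to 1611 units among the arrays. The lowest was that of Mot1-aa 0 min culture 1 alone, with 853.6 for the next lowest array. Its gene spots lay 11.65 times over background, against 22.39 or more on every other array. The median sample background ranged from 34 to 52, and the share of genes above the 99th percentile of the negative spots from 96.05% to 99.72%. The SD between duplicate spots was 0.03 to 0.05 on the log2 scale. With 2 arrays per group, the number of arrays limits the precision.

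One linear model per gene was fitted with limma (lmFit and eBayes) to all 16 arrays, with the 8 groups and a term for dye orientation. This term is the same column as the culture number, so it takes out any difference between culture 1 and culture 2 that all groups share. Cultures of different strains are different cultures, so it does not block on the culture of a single strain. Arrays of a strain at different times were treated as independent. The model leaves 7 residual degrees of freedom, to which eBayes added 3.54 from the other genes. Differences between culture 1 and culture 2 were shared between groups, with a median r of 0.620 across genes over the 28 pairs of groups (range -0.356 to 0.777, 25 pairs over 0.1). The depletion effect at a time is the change from 0 min in Mot1-aa minus the change from 0 min in WT-aa. Further comparisons were each strain against its own 0 min, Mot1-aa against WT-aa at 0 min, and the depletion effect at 30 min minus that at 10 min. Tests were two-sided, p values were adjusted by Benjamini-Hochberg over the 5315 genes of a comparison, and 0.05 was the threshold. Errors beside a fitted change are its SE from limma, and errors beside a group mean are the SD of n = 2 cultures. Overlaps of calls were set against n1×n2/N. Because most of the compared effects share the 0 min arrays, covariances across genes were set against 100 simulations in which no group differed. Such simulations call almost no genes and so give no expected overlap. Their noise was equal on every array.

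The design, 35 gene lists and the rule for naming genes were chosen before the data were examined. The rule takes MOT1 and SPT15; the 6 largest rises and 6 largest falls of each depletion effect that passed with the same sign in both cultures; the 4 largest of each direction for Mot1-aa against WT-aa at 0 min and for WT-aa at 30 min; and up to 3 passing members of each list at 30 min in its main direction, or the member with the smallest p where none passed. Strain marker genes are not named. The 33 lists with at least 5 measured members were tested with camera in limma against all other genes at 3 times, with a preset correlation between genes of 0.01 and, beside it, an estimated correlation, and adjusted over the 99 tests. Counts of members that passed are given over all genes and adjusted over the list alone.

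The alternatives were a fit without the dye term, no background correction, median centring in place of loess, quantile normalization of average intensities between arrays, the authors' ratios, a fit without the dimmest 25% of genes, array weights, scaling on the external control spots in place of loess, a fold of at least 1.7 beside the threshold, the direct contrast of the strains at each time, an estimated correlation for the lists, and leaving out each of the 16 arrays. A fit without both Mot1-aa 10 min arrays was added after seeing the data. The whole procedure was tested on simulated data for the depletion effect at 30 min, over 5315 genes of which 200 were changed. Over 10 simulations it called 90.6% of the genes raised by 1 on the log2 scale and 93.4% of those changed by -1, against 34.2% and 33.8% at 0.5 and -0.5, and on average 5.5 unchanged genes. The simulated noise was independent between genes and equal on every array. The spread between cultures was not equal between groups in the data, so these rates need not hold there. A planned test of genes with and without a promoter TATA box was left out, because no genome sequence was at hand.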

Results

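The data are 16 arrays of newly made RNA, 2 independent cultures of each of 2 strains (Mot1-aa, from whose nucleus rapamycin removes Mot1, and WT-aa, its untagged parent) at 0, 10, 20 and 30 min after rapamycin. Each value is a log2 ratio of the labelled RNA of a gene to that of the same gene in a common WT-aa reference pool, for 5315 genes. Gene spots lay 11.7 to 32.3 times over their background, with 22.4 or more on every array but Mot1-aa 0 min culture 1. That array is the baseline of the Mot1-aa changes of culture 1. It also enters the strain difference at 0 min and every depletion effect. The external control spots lay only 1.15 to 1.50 times over theirs, so a change common to all genes was not measurable. When the arrays were scaled on those spots, the median of all genes in the depletion effect moved to 0.54 at 10 min, 0.54 at 20 min and 0.27 at 30 min. It was -0.61 in the strain difference at 0 min, which enters every depletion effect. Changes are therefore given relative to the typical gene of the arrays. The title of the series sets housekeeping promoters that use TFIID against regulatable promoters that use SAGA. The comparisons ask which genes are made more or less when Mot1 leaves the nucleus, how fast, and whether rapamycin alone or the tag alone has an effect.

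MOT1 (YPL082C), the gene of the depleted protein, stood at -0.75 ± 0.80, -0.95 ± 1.92, -0.40 ± 0.31 and 0.26 ± 0.50 (SD, n = 2) in Mot1-aa at 0, 10, 20 and 30 min. In WT-aa it stood at -0.05 ± 0.06, 0.15 ± 0.14 and 0.16 ± 0.12 at 0, 10 and 20 min, and at 0.12 with an SD of 0.25 at 30 min. No comparison of MOT1 passed the test. Its depletion effect at 30 min was 0.84 (SE 0.79, adjusted p = 0.48 by limma), and its difference between the strains at 0 min was -0.70 (SE 0.56, adjusted p = 0.642). Anchor-away moves the protein and leaves the gene in place, so this probe does not measure the depletion. SPT15 (YER148W), the gene of the TATA-binding protein, had a depletion effect of 0.43 at 30 min (SE 0.15), which did not pass (adjusted p = 0.0675), although it passed without either Mot1-aa 10 min array or Mot1-aa 0 min culture 2 (lowest adjusted p 0.0116).

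Rapamycin and time alone changed few genes in WT-aa. CIT2 (YCR005C), the peroxisomal citrate synthase, rose at every time and by 1.31 on the log2 scale at 30 min (SE 0.07, 2.48-fold, adjusted p = 5.16e-06, n = 2 per group). At 30 min the biotin genes BIO5 (YNR056C), BIO3 (YNR058W) and BIO4 (YNR057C) rose by 1.19 (SE 0.14), 0.87 (SE 0.08) and 0.86 (SE 0.11). FRE4 (YNR060W) and FIT2 (YOR382W), both of iron uptake, fell by 0.70 (SE 0.12) and fell by 0.60 (SE 0.09), and they were the only genes called lower. BIO5, BIO4, FRE4 and FIT2 missed the threshold without WT-aa 0 min culture 1 or 30 min culture 2, with highest adjusted p of 0.105, 0.171, 0.373 and 0.38 over all arrays left out. The last 3 of these genes also missed it without WT-aa 30 min culture 1, BIO4 without WT-aa 0 min culture 2, FRE4 and FIT2 without either WT-aa 20 min array, and FRE4 without any Mot1-aa array of 0 or 20 min. FRE4 and FIT2 also missed it without the dye term and with median centring, and FIT2 with the authors' values. At 10 min 20 genes rose and 2 fell, at 20 min 6 rose and 0 fell, and at 30 min 19 rose and 2 fell (limma). An unadjusted p under the threshold was found for 399, 243 and 461 genes, where chance gives 266. Of the genes higher at 10 min, 8 were also higher at 30 min, against 0.0715 from n1×n2/N, which leaves out that both changes share the 0 min arrays. The covariance across genes was 0.0133, against 0.00712 in simulated groups that share them, with equal noise on every array. Array weights gave the shared WT-aa 0 min arrays 0.605, the lowest in WT-aa. The simulated covariance can therefore be too low, and the excess does not show a lasting change.

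Other genes of WT-aa are named here although they were chosen after their values were seen. The 6 genes higher at 20 min were CIT2, CIT1, ACO1, AGP2, DLD3 and SRL3, with changes from 0.41 for SRL3 to 1.05 for CIT2. CIT1 and ACO1 act with CIT2 in the citrate and glyoxylate pathways; CIT1 rose by 0.74 and ACO1 by 0.72 at 20 min. GLN1 and GDH1, which make glutamine and glutamate, rose at 10 min by 1.13 (SE 0.13) and 0.94 (SE 0.10) and stood at 0.20 and 0.36 at 30 min, where neither passed (adjusted p = 0.687 and 0.305). AAH1 and YMC1 were the 2 genes lower at 10 min, with changes of -0.40 and -0.37. The counts at 10, 20 and 30 min were 73, 39 and 111 without either Mot1-aa 10 min array, and 9, 3 and 9 without the dye term. With other arrays left out, the 10 min count was 10 without WT-aa 0 min culture 1, and 6 and 4 without WT-aa 10 min cultures 1 and 2. The 30 min count was 5 and 12 without WT-aa 0 min cultures 1 and 2, 5 and 4 without WT-aa 30 min cultures 1 and 2, and 11 without either WT-aa 20 min array. The 20 min count was 10 without WT-aa 0 min culture 2, and 3 without each other array except WT-aa 20 min culture 2 and those of Mot1-aa at 0 and 10 min.

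Before rapamycin, Mot1-aa already differed from WT-aa. WSC4 (YHL028W), a cell wall stress sensor of the endoplasmic reticulum, was higher in Mot1-aa by 1.65 on the log2 scale (SE 0.18, 3.13-fold), and BNA4 (YBL098W), an enzyme of NAD synthesis, by 1.57 (SE 0.09, 2.96-fold, adjusted p = 2.76e-05). YLR112W and ARO10 (YDR380W), a decarboxylase of amino acid breakdown, were higher by 1.37 (SE 0.11) and 1.35 (SE 0.16). The iron uptake genes FIT2, ENB1 (YOL158C) and FRE4 were lower, with differences of -1.34 (SE 0.09), -1.22 (SE 0.08) and -1.09 (SE 0.12), as was the multidrug transporter FLR1 (YBR008C) at -1.0 (SE 0.17). Among genes that the naming rule gives for the depletion effect, HSP26 was higher at 0 min by 1.16 (SE 0.10), ALD4 by 1.03 (SE 0.08) and ARG3 by 0.90 (SE 0.12), while TIS11 differed by -0.90 (SE 0.12). In all, 98 genes were higher and 45 lower in Mot1-aa at 0 min (limma, 143 of 5315, n = 2 per group). Of the 98, 97 were also higher in Mot1-aa than in WT-aa at 30 min, and 32 of the 45 were also lower. Independent calls would give 24.4 and 10.9 (n1×n2/N). In opposite directions 1 gene was called, and the covariance was 0.0558 against 4.71e-05 in simulated groups without differences. The 30 min comparison contains any lasting difference between the strains, which gives such an overlap without a response to rapamycin. These counts therefore do not show that Mot1-aa at 0 min resembles the depleted state.

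The difference between the strains at 0 min includes whatever else differed between both sets of cultures. The count of 143 was 55 without the dye term, 48 without Mot1-aa 0 min culture 1 and 67 without WT-aa 0 min culture 1. It was 93 without either WT-aa 10 min array, 425 without either Mot1-aa 10 min array and 4 with scaling on the external control spots, where the split turned to 0 higher and 4 lower and the median of all genes was -0.61. Of the genes named, FLR1 missed the threshold without Mot1-aa 0 min culture 1 or WT-aa 0 min culture 1 (highest adjusted p 0.11), and without the dye term.

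In Mot1-aa alone, 184 genes differed from 0 min at 10 min (163 higher, 21 lower), 1270 at 20 min (873 higher, 397 lower) and 2225 at 30 min (1215 higher, 1010 lower). BIO5 rose by 1.08 at 10 min (SE 0.14). Outside the rule and chosen after their values were seen, RSB1 and AGP1 rose by 1.28 (SE 0.14) and 1.18 (SE 0.07), while the ribosome assembly gene RLP24 fell by 0.57 (SE 0.11). CIT2, the gene with the largest rise in WT-aa at 30 min, rose in Mot1-aa too, by 1.21 at 30 min (SE 0.07), and its depletion effect was -0.10 (SE 0.09, adjusted p = 0.464). PHM8, HSP26 and MTD1 rose by 2.39 (SE 0.19), 2.15 (SE 0.10) and 1.75 (SE 0.07) at 30 min. Of the genes higher at 10 min, 161 were higher at 30 min too, and all 21 genes lower at 10 min were lower at 30 min. Independent calls would give 37.3 and 3.99 (n1×n2/N), but both changes share the 0 min arrays. The covariance was 0.0607, against 0.00708 in simulated groups that share them.

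Across genes, the changes in both Mot1-aa cultures went together at 20 min (r = 0.816) and 30 min (r = 0.906) but not at 10 min (r = -0.0583); genes are not independent replicates. The 10 min count was 1233 and 496 without Mot1-aa 10 min cultures 1 and 2, 55 and 120 without Mot1-aa 0 min cultures 1 and 2, and 113 without either WT-aa 10 min array. It was 44 without the dye term, 120 with median centring, 2 with array weights and 5 with scaling on the external control spots. The 20 min count was 674 without Mot1-aa 0 min culture 1, 808 and 608 without Mot1-aa 20 min cultures 1 and 2, 1973 without either Mot1-aa 10 min array and 689 without the dye term. The 30 min count was 1461 without Mot1-aa 0 min culture 1, 1298 without Mot1-aa 30 min culture 1 and 1472 without the dye term. With scaling on the external control spots the split was 616 higher and 0 lower at 20 min and 784 higher and 2 lower at 30 min, where the median of all genes was 0.40 and 0.36.

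**Figure D1:**
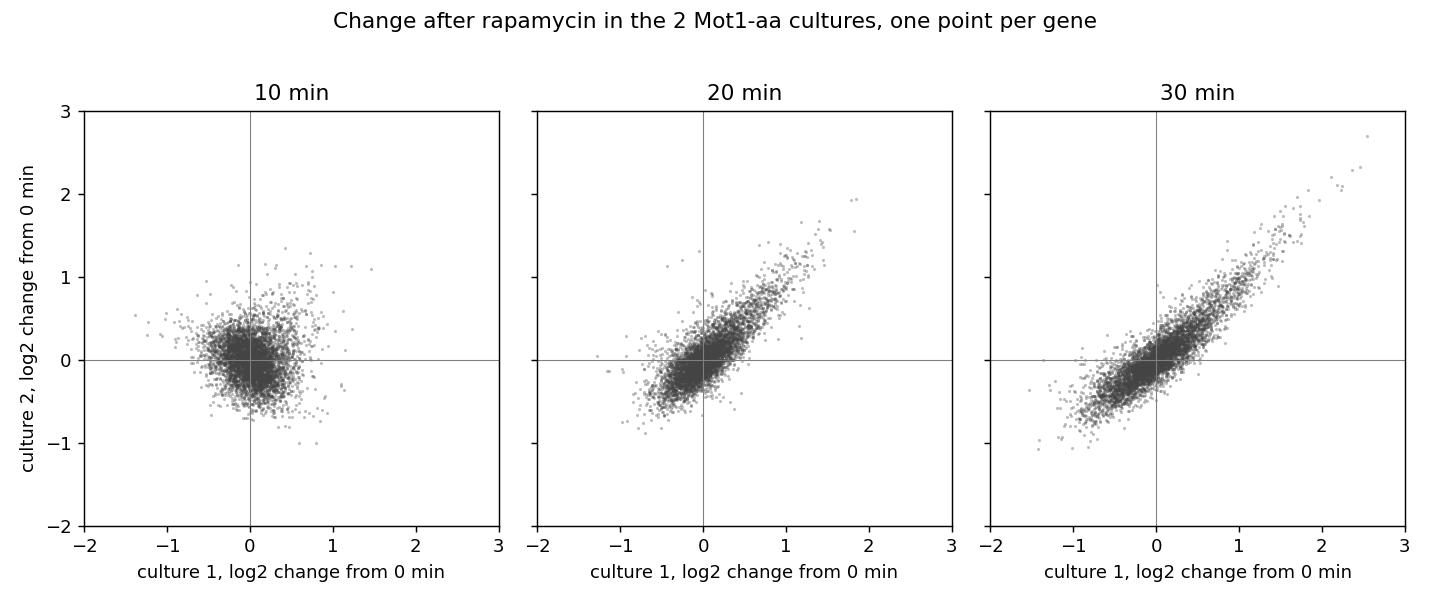
Change from 0 min in culture 1 (x axis, log2) against culture 2 (y axis, log2) of Mot1-aa at 10, 20 and 30 min, with one point per gene for 5315 genes. The points lie along the diagonal at 20 min (r = 0.816) and 30 min (r = 0.906), and form a round cloud at 10 min (r = -0.0583).

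At 10 min no gene passed as a depletion effect. PHM8 stood at 0.63 (SE 0.27), TIS11 at 0.67 (SE 0.17) and MTD1 at 0.37 (SE 0.09, adjusted p = 0.92). The smallest adjusted p over all genes was 0.111. limma called 0 of 5315 genes, with 225 at an unadjusted p under the threshold where chance gives 266. The general stress list had a positive depletion effect in 32 of its 38 members, and camera called it (median 0.13, adjusted p = 9.79e-05). It also called the seripauperins (median 0.31, 16 of 16 members positive, adjusted p = 8.13e-15) and ergosterol genes (median 0.19, 23 of 24, adjusted p = 2.29e-08). Ribosome biogenesis genes had a negative effect in 49 of 57 members. Their median was -0.11, or 0.54 with scaling on the external control spots, where that of all genes was 0.54 (camera adjusted p = 5.49e-06). With an estimated correlation these adjusted p were 0.196, 0.155, 0.0798 and 0.196. The stress list was not called without WT-aa 0 min culture 2 (adjusted p = 0.788), nor the ribosome biogenesis list without Mot1-aa 10 min culture 2 (adjusted p = 0.19), nor either of them with median centring. Without Mot1-aa 10 min culture 1 the count of genes was 18, without culture 2 it was 1, and the direct contrast of the strains at 10 min, which includes their difference at 0 min, called 514.

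At 20 min 430 genes had a depletion effect, 375 of them higher and 55 lower. PHM8 (YER037W), a phosphatase gene of the phosphate and starvation response, rose by 1.66 on the log2 scale (SE 0.27, 3.17-fold, adjusted p = 0.00553, n = 2 per group). MTD1 (YKR080W), a folate enzyme, rose by 1.47 (SE 0.09, 2.77-fold, adjusted p = 7.1e-05). CAR2 (YLR438W) of arginine breakdown rose by 1.41 (SE 0.34), ADE17 (YMR120C) of purine synthesis by 1.32 (SE 0.15), YGR035C by 1.30 (SE 0.27) and the polyamine oxidase FMS1 (YMR020W) by 1.27 (SE 0.15). The largest falls were smaller: SWM1 (YDR260C), a subunit of the anaphase-promoting complex, fell by 0.85 (SE 0.20), IES5 (YER092W) of the INO80 complex fell by 0.73 (SE 0.17) and LGE1 (YPL055C) fell by 0.68 (SE 0.17). RCL1 (YOL010W), an rRNA processing gene, fell by 0.62 (SE 0.14), GDS1 (YOR355W) fell by 0.60 (SE 0.13) and URM1 (YIL008W), a ubiquitin-like modifier, fell by 0.59 (SE 0.13).

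The split at 20 min leant to rises, and all 16 seripauperins rose (median 0.87, 16 adjusted over the list alone, camera adjusted p = 3.49e-18; adjusted p = 0.143 with an estimated correlation). The count of 430 was 86 without the dye term, all of them rises, 244 with median centring and 709 with array weights. It was 0 with scaling on the external control spots (limma; 1086 genes at an unadjusted p under the threshold in the fit reported). It was 827 without either Mot1-aa 10 min array, 179 without Mot1-aa 0 min culture 1, 261 without WT-aa 0 min culture 1, 238 and 131 without Mot1-aa 20 min cultures 1 and 2, and 196 and 102 without WT-aa 20 min cultures 1 and 2. PHM8, MTD1, ADE17 and FMS1 passed whichever array was left out. CAR2, YGR035C and the 6 falls missed the threshold without culture 2 of either strain at 20 min, and without the dye term, with highest adjusted p from 0.0883 for YGR035C to 0.17 for LGE1. All of these but YGR035C also missed it without Mot1-aa 20 min culture 1, all but GDS1 without Mot1-aa 0 min culture 1, and CAR2, SWM1 and LGE1 even without a Mot1-aa 30 min array.

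At 30 min 1120 genes had a depletion effect, 721 higher and 399 lower. PHM8 rose by 2.26 (SE 0.27, 4.80-fold, adjusted p = 4.22e-04), from 0.13 ± 0.17 at 0 min to 2.52 ± 0.08 at 30 min in Mot1-aa (SD, n = 2). It stood at -0.51 ± 0.18 and -0.39 ± 0.17 in WT-aa. The chaperone genes HSP26 (YBR072W) and SSA4 (YER103W) rose by 2.08 (SE 0.15, 4.23-fold) and 1.96 (SE 0.21, 3.90-fold). BDH2 (YAL061W), a putative butanediol dehydrogenase, rose by 1.96 (SE 0.20), the stress-induced RTC3 (YHR087W) by 1.95 (SE 0.27) and MTD1 by 1.90 (SE 0.09, adjusted p = 5.05e-06). SSS1 (YDR086C), a subunit of the Sec61 translocon, fell by 1.30 (SE 0.25, adjusted p = 0.00535). TRM112 (YNR046W), a partner of RNA and protein methyltransferases, fell by 1.12 (SE 0.19), and UTP14 (YML093W), needed for the small ribosomal subunit, fell by 1.07 (SE 0.11). DFR1 (YOR236W), dihydrofolate reductase, fell by 1.06 (SE 0.20), TMN2 (YDR107C) fell by 1.01 (SE 0.23) and RRP8 (YDR083W), an rRNA methyltransferase, fell by 1.00 (SE 0.21). BNA4, already 2.96-fold higher in Mot1-aa at 0 min, rose by a further 1.03 (SE 0.13), and WSC4 by 1.03 (SE 0.25). TMN2 missed the threshold without Mot1-aa 0 or 30 min culture 1 or WT-aa 30 min culture 2 (highest adjusted p 0.0605). WSC4 missed it without Mot1-aa 0 min culture 2, Mot1-aa 30 min culture 1 or either WT-aa 30 min array (0.0674), and RRP8 without the dye term.

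Of the genes higher at 20 min, 365 were higher at 30 min too, and 54 of the 55 lower genes were lower. Independent calls would give 50.9 and 4.13 (n1×n2/N), but both effects share the 0 min arrays. The covariance across genes was 0.103 against 0.0143 simulated. The count of 1120 was 463 without the dye term (353 higher, 110 lower), 696 with median centring and 4 with scaling on the external control spots. It was 2008 without either Mot1-aa 10 min array, 640 without Mot1-aa 0 min culture 1, 708 without WT-aa 0 min culture 2, 578 and 709 without Mot1-aa 30 min cultures 1 and 2, and 692 and 536 without WT-aa 30 min cultures 1 and 2.

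**Figure D2:**
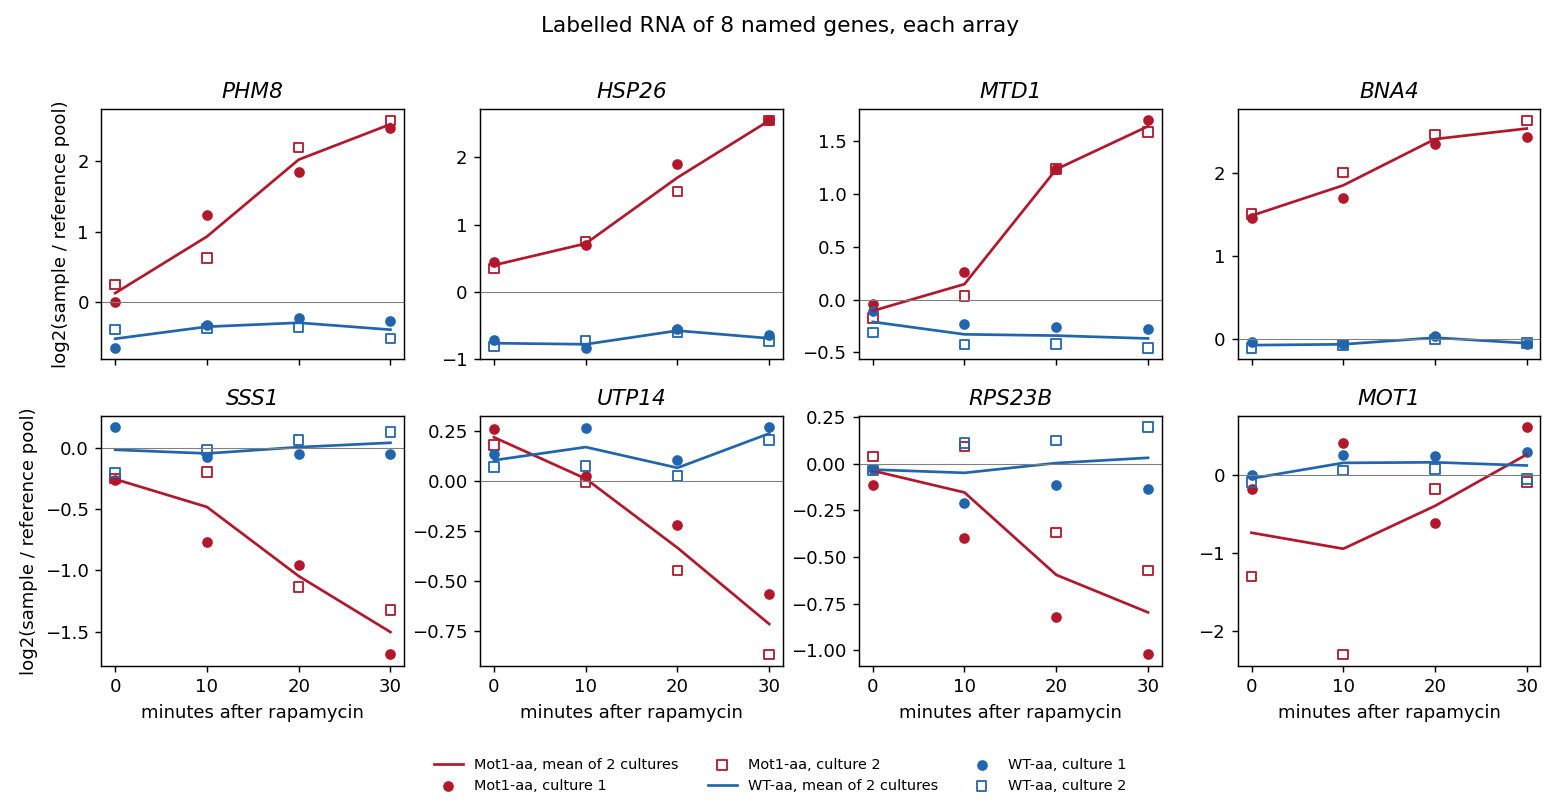
Labelled RNA of 8 genes, as log2(sample/reference pool) on the y axis, against minutes after rapamycin on the x axis, with Mot1-aa in red and WT-aa in blue; lines join the means of 2 cultures, filled circles are culture 1 and open squares culture 2. PHM8, HSP26, MTD1 and BNA4 climbed in Mot1-aa, SSS1, UTP14 and RPS23B declined, and the MOT1 cultures at 10 min lay far apart (-0.95 ± 1.92).

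Among the gene lists, 18 of the 33 tested were called at 30 min by camera with the preset correlation, and none with an estimated correlation. Over all genes 21.07% passed at 30 min in either direction, which is the share to set beside members that passed in either direction. Of the 5315 genes 721 rose and 399 fell, and counts of rises or of falls alone are to be set beside these. General stress genes, which answer to Msn2 and Msn4, were called with the largest median. Of 38 measured members 31 rose, 0 fell and 7 did not pass (33 rose adjusted over the list alone). The median depletion effect was 0.94 (camera adjusted p = 3.89e-17; adjusted p = 0.0798 with an estimated correlation). MSC1 (YML128C) rose by 1.90 (SE 0.18), the catalase CTT1 (YGR088W) by 1.83 (SE 0.12) and the glycogen phosphorylase GPH1 (YPR160W) by 1.65 (SE 0.16). Of 23 heat shock and chaperone genes, 6 rose and 17 did not pass (6 adjusted over the list alone; median 0.33, adjusted p = 0.00153; adjusted p = 0.454 with an estimated correlation), among them HSP42 (YDR171W), by 1.05 (SE 0.21). All 16 seripauperins, cell wall mannoproteins of near-identical sequence whose probes are not independent, rose (16 adjusted over the list alone; median 0.88, adjusted p = 1.28e-12; adjusted p = 0.196 with an estimated correlation), such as PAU22 (YPL282C) by 1.08 (SE 0.10). Of 16 oxidative stress genes, 5 rose (8 adjusted over the list alone; median 0.40, adjusted p = 0.00314; adjusted p = 0.333 with an estimated correlation). Among them were GPX2 (YBR244W) at 0.79 (SE 0.24), GLR1 (YPL091W) at 0.71 (SE 0.12) and ATR1 (YML116W) at 0.64 (SE 0.14). GPX2 missed the threshold without any of 11 arrays, those of Mot1-aa at 0, 20 and 30 min among them (highest adjusted p 0.188) and without the dye term, and ATR1 without WT-aa 30 min culture 2 (0.0513).

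Lipid genes were called as well. Of 24 ergosterol genes 17 rose and 7 did not pass (18 adjusted over the list alone), with a median of 0.55 (adjusted p = 2.58e-08; adjusted p = 0.0798 with an estimated correlation). ERG28 (YER044C) rose by 1.20 (SE 0.14), ERG20 (YJL167W) by 1.12 (SE 0.21) and MVD1 (YNR043W) by 1.02 (SE 0.15). Of 11 phospholipid and fatty acid genes 5 rose (5 adjusted over the list alone; median 0.40, adjusted p = 0.00368; adjusted p = 0.155 with an estimated correlation). Among them were INO1 (YJL153C) at 1.11 (SE 0.13), ACC1 (YNR016C) at 0.84 (SE 0.14) and PSD1 (YNL169C) at 0.70 (SE 0.15). Of 12 drug efflux genes 4 rose (4 adjusted over the list alone; median 0.31, adjusted p = 0.0393; adjusted p = 0.333 with an estimated correlation). Among them were SNQ2 (YDR011W) at 0.94 (SE 0.23), ICT1 (YLR099C) at 0.92 (SE 0.14) and RSB1 (YOR049C) at 0.70 (SE 0.20). The drug efflux list was not called without Mot1-aa 0 min culture 2, Mot1-aa 30 min culture 1, or culture 1 of WT-aa at 0 or 30 min (highest adjusted p 0.129). SNQ2 and RSB1 missed the threshold without culture 1 of Mot1-aa or culture 2 of WT-aa at 0 or 30 min (0.0802 and 0.137), RSB1 also without other WT-aa arrays, without the dye term and with median centring. PSD1 missed it without the dye term and with the authors' values.

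Of 25 iron regulon genes 13 rose and 12 did not pass (13 adjusted over the list alone; median 0.66, adjusted p = 1.03e-04; adjusted p = 0.0798 with an estimated correlation). TIS11 (YLR136C), which triggers decay of mRNAs of iron-using proteins, rose by 1.74 (SE 0.17), the haem oxygenase HMX1 (YLR205C) by 1.44 (SE 0.24) and FRE4 by 0.91 (SE 0.16). TIS11 and FRE4 were lower in Mot1-aa than in WT-aa at 0 min. The FRE4 effect combines a change of 0.21 (SE 0.12, adjusted p = 0.168) in Mot1-aa with the change of -0.70 in WT-aa.

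Carbon and nitrogen lists were called too. Of 35 respiratory chain and ATP synthase genes 12 rose (12 adjusted over the list alone; median 0.29, adjusted p = 4.32e-04; adjusted p = 0.259 with an estimated correlation). Among them were CYC1 (YJR048W) at 1.09 (SE 0.13), SDH2 (YLL041C) at 1.06 (SE 0.25) and CYC7 (YEL039C) at 1.04 (SE 0.12). Of 13 hexose transporter genes 7 rose (8 adjusted over the list alone; median 0.39, adjusted p = 0.0071; adjusted p = 0.141 with an estimated correlation). Among them were HXT2 (YMR011W) at 0.78 (SE 0.22), HXT5 (YHR096C) at 0.53 (SE 0.09) and HXT6 (YDR343C) at 0.51 (SE 0.14). Of 16 genes of glycolysis and ethanol formation 3 rose (3 adjusted over the list alone; median 0.30, adjusted p = 0.00483; adjusted p = 0.27 with an estimated correlation): TPI1 (YDR050C), CDC19 (YAL038W) and PGI1 (YBR196C), by 0.62, 0.56 and 0.46. Of 24 nitrogen catabolite genes, which answer to TOR, 8 rose (9 adjusted over the list alone; median 0.18, adjusted p = 0.00902; adjusted p = 0.143 with an estimated correlation). Among them were ECM38 (YLR299W) at 1.40 (SE 0.11), UGA1 (YGR019W) at 1.14 (SE 0.15) and GAP1 (YKR039W) at 0.95 (SE 0.14). The glycolysis list was not called without WT-aa 0 min culture 1 (adjusted p = 0.0799), nor the nitrogen list without the dimmest genes. SDH2, HXT2, HXT6 and CDC19 missed the threshold without either Mot1-aa 30 min array, and without further arrays of 0 and 30 min (highest adjusted p 0.0742, 0.0953, 0.123 and 0.0858). Without the dye term HXT2, HXT6, TPI1, CDC19 and PGI1 missed it, with median centring HXT2 and HXT5, and with the authors' values HXT6 and PGI1.

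Genes of protein synthesis were called in the other direction. Of 126 ribosomal protein genes 31 fell, 0 rose and 95 did not pass (40 fell adjusted over the list alone). Their median was -0.39 and became 0.03 with scaling on the external control spots, where the median of all genes was 0.27 (camera adjusted p = 6.89e-16; adjusted p = 0.196 with an estimated correlation). RPS23B (YPR132W) fell by 0.82 (SE 0.16), RPL39 (YJL189W) fell by 0.77 (SE 0.22) and RPS23A (YGR118W) fell by 0.74 (SE 0.18). Of 57 ribosome biogenesis genes 19 fell (20 adjusted over the list alone), with a median of -0.28 that also became 0.03 under that scaling (adjusted p = 3.82e-07; adjusted p = 0.155 with an estimated correlation). NOP15 (YNL110C) fell by 0.84 (SE 0.20), NOP56 (YLR197W) fell by 0.79 (SE 0.12) and SOF1 (YLL011W) fell by 0.76 (SE 0.11). Of 23 translation factor genes 5 fell (5 adjusted over the list alone), with a median of -0.24, or 0.13 under that scaling (adjusted p = 0.00153; adjusted p = 0.333 with an estimated correlation). Among them were TIF35 (YDR429C) at -0.70 (SE 0.16), PAB1 (YER165W) at -0.68 (SE 0.15) and TEF2 (YBR118W) at -0.54 (SE 0.16). RPL39, RPS23A, NOP15, TIF35 and TEF2 missed the threshold without culture 1 of Mot1-aa at 0 or 30 min, among other arrays (highest adjusted p 0.133, 0.0757, 0.0697, 0.0576 and 0.166), PAB1 without WT-aa 30 min culture 2 (0.0513), and RPS23B without the dye term. RPL39, RPS23A, NOP15 and TEF2 also missed it without the dye term, and RPL39, RPS23A and TEF2 with median centring. TEF2 missed it with the authors' values too. With scaling on the external control spots none of these genes passed, and the translation factor list was not called.

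Of 55 genes listed as mitochondrial ribosomal proteins 8 fell and 1 rose (3 fell and 1 rose adjusted over the list alone), with a median of -0.16, or 0.13 under that scaling (adjusted p = 0.00172; adjusted p = 0.333 with an estimated correlation). MRPL28 (YDR462W) fell by 0.57 (SE 0.18), MRPS16 (YPL013C) fell by 0.57 (SE 0.11) and MRP49 (YKL167C) fell by 0.49 (SE 0.11). The riser, MRP8 at 0.71, was chosen after its value was seen and, despite its name, is not known as a mitochondrial ribosomal protein. Of 33 proteasome genes 5 fell (4 adjusted over the list alone), with a median of -0.07, or 0.26 under that scaling (adjusted p = 0.0152; adjusted p = 0.455 with an estimated correlation). Among them were RPT3 (YDR394W) at -0.47 (SE 0.12), PRE4 (YFR050C) at -0.46 (SE 0.09) and RPT1 (YKL145W) at -0.46 (SE 0.11). Of 32 genes of TBP, of Mot1 and of the factors that act with TBP (NC2, TFIIA, TFIIB, TFIID and SAGA), 3 fell (2 adjusted over the list alone), with a median of -0.15, or 0.10 under that scaling (adjusted p = 0.0367; adjusted p = 0.155 with an estimated correlation). These were GCN5 (YGR252W) of SAGA, TOA1 (YOR194C) of TFIIA and HFI1 (YPL254W) of SAGA, at -0.51 (SE 0.12), -0.44 (SE 0.13) and -0.41 (SE 0.10). The proteasome list was not called without culture 1 of either strain at 30 min (highest adjusted p 0.0691), with median centring or with scaling on the external control spots. This last list was not called without culture 1 of either strain at 0 min, without culture 2 of either at 30 min (0.119), or without the dimmest genes. MRPL28, MRP49, RPT3, RPT1, GCN5 and TOA1 missed the threshold without Mot1-aa 0 or 30 min culture 1 or WT-aa 30 min culture 2, and most also without other arrays (0.19, 0.0564, 0.0768, 0.0786, 0.0626 and 0.141). HFI1 missed it without Mot1-aa 30 min culture 2 or WT-aa 30 min culture 1 (0.0654). Without the dye term MRPL28, MRPS16, RPT3, RPT1, GCN5, TOA1 and HFI1 missed it, with median centring MRPL28, RPT3, PRE4 and RPT1, and with the authors' values RPT1 and HFI1.

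**Figure D3:**
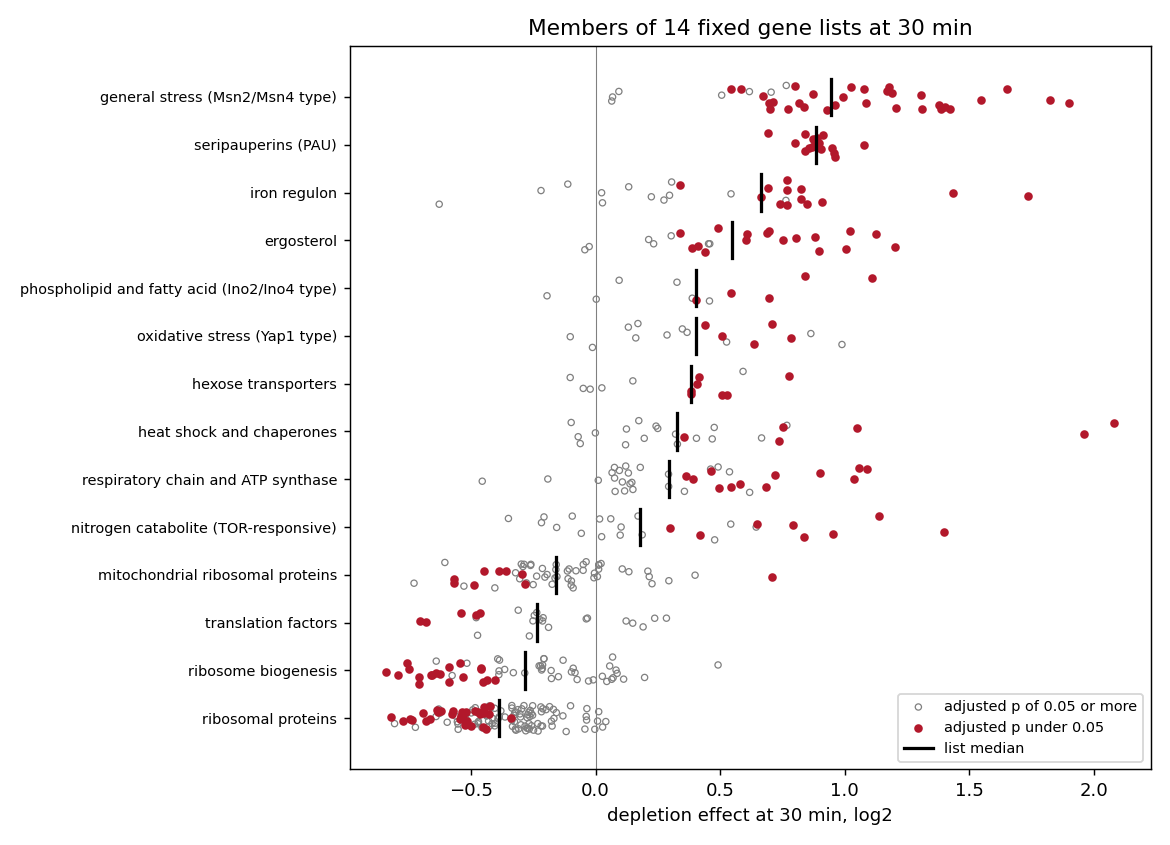
Depletion effect at 30 min (x axis, log2) of each member of 14 gene lists (y axis), with filled red points for members that passed, open points for those that did not, and a black bar at the list median. Stress, seripauperin, iron and lipid lists lie to the right (medians 0.94, 0.88, 0.66 and 0.55 for general stress, seripauperins, iron and ergosterol). Ribosomal protein genes lie to the left (median -0.39, or 0.03 with scaling on the external control spots, which also moves the other 3 lists on the left to between 0.03 and 0.13).

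Whether the depletion effect grew was tested directly. It differed between 30 and 10 min for 540 genes, 372 of them higher and 168 lower at 30 min, and between 20 and 10 min for 23. Without the dye term limma called 0 genes between 20 and 10 min (562 at an unadjusted p under the threshold in the fit reported). The gain from 10 to 30 min was 1.76 for BDH2, 1.74 for HSP26, 1.69 for CTT1, 1.64 for RTC3 and 1.63 for PHM8. The loss was -1.11 for SSS1, -1.01 for DFR1 and -1.0 for TRM112. Between 20 and 30 min limma called 0 genes, with 296 at an unadjusted p under the threshold where chance gives 266. The count of 540 was 137 without the dye term, 308 with median centring, 168 with array weights and 0 with scaling on the external control spots. It was 2364 without Mot1-aa 10 min culture 1, 207 and 227 without Mot1-aa 30 min cultures 1 and 2, 193 and 175 without WT-aa 10 min cultures 1 and 2, and 270 and 158 without WT-aa 30 min cultures 1 and 2.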

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

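Of the tests in this part, the matching of ribosomal protein genes on intensity, and on intensity with coding length, was set out before its result was seen. Every other test of an explanation was chosen after the result was seen. No single array was tested against its group, since groups of 2 are too small for that.

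The first pattern is that the 2 Mot1-aa cultures at 10 min changed in unrelated ways across genes (r = -0.0583), against r of 0.816 and 0.906 at 20 and 30 min. An exchange of the 0 and 10 min labels in culture 2 is argued against by a positive r of 0.333 between its 10 min change and the 30 min change of culture 1, and an exchange with WT-aa at 30 min by a slope of only 0.0408 of that array's change on the Mot1-aa 30 min change. Removing trends in coding length and intensity left r at -0.0541, and slower depletion in culture 2, a biological explanation, is argued against as the whole cause by an r of -0.165 between the culture difference at 10 min and the 30 min change. What stays open is a component shared with WT-aa 30 min culture 2 (r = 0.763 between the culture differences of both groups, with 0.824 for a pair that has no such link), and any other difference in handling, for which the labels give no batch. Without culture 1 of this group the 10 min depletion effect called 18 genes, and without culture 2 it called 1, in place of 0.

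The second pattern is that Mot1-aa before rapamycin resembled Mot1-aa after it in part across genes, although TIS11 and FRE4 were displaced the other way. To keep arrays from being shared, the strain difference of one culture was set against the later Mot1-aa change of the other, and the lowest of the 4 r across genes at 20 and 30 min was 0.313 (at 10 min, where the cultures disagree, r was 0.149 and -0.0551), where a constant gene-specific dye effect cancels within a culture and would give about 0. With trends in coding length and intensity removed the lowest was 0.324, and the lowest r exceeded the highest r with the WT-aa change by 0.325. A candidate explanation, chosen after the result was seen, is that the tag already costs Mot1 part of its function, a hypothesis that the r at 20 and 30 min, but not those at 10 min, are in line with. It remains open beside a dye effect that varies between arrays and other differences between the strains' cultures, such as their growth state, which no label gives.

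The third pattern is the fall of ribosomal protein genes at 30 min, with a median of -0.39. Among 10000 lists of other genes matched on intensity, the share with a median as low was 0%, and 95% of their medians lay between 0.09 and 0.27; matched on coding length too, it was again 0%, between 0.03 and 0.24. The members never saturated, all but 3, had a median of -0.39, so the tested technical causes are argued against as the whole source of the gap to matched genes. Loess centres genes of like intensity near 0, so the matched lists, taken after loess, do not test the size of the fall. With median centring in place of loess the median was -0.31, where that of all genes was -0.06. That the fall follows Mot1 depletion may be biological, as a hypothesis only: the list's adjusted p was 0.196 with an estimated correlation, and whether these genes answer to Mot1 directly was not tested. On the scale of the external control spots the median was 0.03. Those spots lay near their background, so they cannot show whether the fall is absolute, and it is given relative to other genes.

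The next results stand out because a test found a difference between groups: between the changes of the strains, or between times. The depletion effect called 430 genes at 20 min and 1120 at 30 min, against 0 at 10 min (limma; 225 at an unadjusted p under the threshold), and the test of the difference between 30 and 10 min called 540 genes. Of the 119 genes that the naming rule gives, 67 differed between 30 and 10 min, 52 of them higher and 15 lower at 30 min. The rule favours such genes, since it takes large or passing effects at 30 min, and over all genes the share was 10.2%. The following differences are the 30 min effect minus the 10 min effect, in log2.

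Among genes of stress, chaperones, redox enzymes and the phosphate regulon the difference was 1.63 for PHM8, 1.74 for HSP26, 1.76 for BDH2, 1.42 for SSA4, 1.64 for RTC3, 1.61 for MSC1, 1.69 for CTT1 and 1.32 for GPH1. It was 0.89 for GPX2, 0.64 for GLR1, 0.74 for ATR1 and 0.42 for SIL1. In amino acid, sulfur, nitrogen and folate or purine metabolism it was 1.53 for MTD1, 1.21 for CAR2, 1.38 for ADE17, 0.88 for FMS1, 0.84 for ARO10 and 1.07 for ARG3. It was 0.62 for LYS9, 0.59 for LYS1, 0.97 for ECM38, 1.01 for UGA1, 0.96 for GAP1, 0.77 for MET3, 0.55 for MET14 and 0.48 for MET10. In carbon use and respiration it was 0.49 for HXT5, 0.59 for HXT6, 0.78 for ALD4, 0.66 for ACH1, 0.70 for GCY1, 0.60 for CYC1 and 0.95 for CYC7.

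In lipid synthesis the difference was 0.69 for ERG28, 0.89 for ERG20, 0.59 for MVD1, 0.90 for INO1 and 0.65 for ACC1. For iron genes it was 1.06 for TIS11, 0.93 for HMX1 and 0.81 for FRE4. For genes already higher in Mot1-aa at 0 min it was 0.67 for BNA4 and 0.64 for YLR112W. Seripauperins gave 0.75 for PAU22, 0.66 for PAU8 and 0.71 for PAU1. Genes of the cell cycle, mating and sporulation gave 0.49 for PCL1, 0.60 for RNR1, 0.57 for CLB1, 0.61 for PRM1, 0.69 for RIM4 and 0.50 for SPS4.

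Differences were negative for SSS1 (-1.11), TRM112 (-1.0), UTP14 (-0.80), DFR1 (-1.01), TMN2 (-0.85), RRP8 (-0.78) and URM1 (-0.47). They were also negative for RPS23B (-0.72), RPS23A (-0.68), MRPS16 (-0.43), NOP56 (-0.72), SOF1 (-0.59), PAB1 (-0.67), RPT3 (-0.42) and PRE4 (-0.35).

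Probes to which the platform gives no gene name were not used in the comparisons, and some of them changed too. Of 1062 such probes, limma called 37 for the depletion effect at 20 min, all higher, and 102 at 30 min (80 higher, 22 lower), against 1 at 10 min, 0 for WT-aa at 30 min and 12 for the strain difference at 0 min. Genes with a name were called at a higher share, 8.09% at 20 min and 21.07% at 30 min.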

How the results depend on the processing

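One test here was chosen after the data were seen, the fit without both Mot1-aa 10 min arrays; the others were planned. Among genes called both in the fit reported and in an alternative fit, none had opposite directions at 20 min, at 30 min or between the strains at 0 min. Calls lost in an alternative fit are not covered by this. Scaling on the external control spots left only 0, 4 and 4 of these calls. It also turned the sign of 5 values of named genes that passed, which are given below. Array weights, and fits without the dye term, the dimmest genes or an array outside the comparison, leave the effects as they are. Those fits could not turn a direction. Of the 190 values of named genes that passed, 186 still passed without background correction, 169 with the authors' values, 145 with median centring, 101 without the dye term and 7 with scaling on the external control spots. Counts moved much more, and the cause was not tested unless stated. Below, depletion counts are for 10, 20 and 30 min in turn. Without the dye term the depletion counts were 0, 86 and 463, and those of Mot1-aa against 0 min 44, 689 and 1472. Those of WT-aa were 9, 3 and 9, the strain difference at 0 min 55, and the difference between 30 and 10 min 137. Fold changes are the same in this fit, and the spread between cultures is larger. With median centring they were 244 and 696 at 20 and 30 min, 120 for Mot1-aa at 10 min, 7 and 10 for WT-aa at 10 and 30 min, and 308 for 30 against 10 min. With array weights, which gave the Mot1-aa 10 min arrays 0.148, they were 709 at 20 min, 2 for Mot1-aa at 10 min, 68 and 38 for WT-aa at 10 and 20 min, and 168 for 30 against 10 min. The authors' values gave 11 for WT-aa at 20 min, 9 higher and 2 lower. Scaling on the external control spots gave 0 and 4 at 20 and 30 min, 5, 616 and 786 for Mot1-aa, 0, 0 and 0 for WT-aa, 4 for the strain difference and 0 for 30 against 10 min. These spots lay only 1.15 to 1.50 times over background, which limits this scale. A fold of at least 1.7 in addition, a stricter rule by construction, left 117 and 312, then 20, 193 and 393 for Mot1-aa, 6, 1 and 5 for WT-aa, 31 for the strain difference and 134 for 30 against 10 min. The direct contrast of the strains, which includes their difference at 0 min, gave 514, 1692 and 2610. Without both Mot1-aa 10 min arrays the counts were 827 and 2008, 1973 for Mot1-aa at 20 min, 73, 39 and 111 for WT-aa, and 425 for the strain difference. The 20 and 30 min depletion effects and the strain difference themselves stayed the same (r = 1, median shift 0), so only the spread estimate changed. The SD of the culture difference was 0.386 for Mot1-aa at 10 min and 0.154 to 0.248 in the other groups. All groups share 1 spread per gene, so counts and SEs rest on an equality that these SDs do not show. Quantile normalization of average intensities leaves log ratios as they are and so tests nothing here.

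Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 0 to 18 genes for the depletion effect at 10 min, 102 to 827 at 20 min and 536 to 2008 at 30 min. The ranges were 55 to 1233, 608 to 1973 and 1298 to 2959 for Mot1-aa, 4 to 73, 3 to 39 and 4 to 111 for WT-aa, 48 to 425 for the strain difference and 158 to 2364 for 30 against 10 min. Each highest count came from leaving out a Mot1-aa 10 min array. With other arrays left out the highest depletion counts were 373 and 1084 at 20 and 30 min.

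Of the 52 list calls over 3 times (38 for rises, 14 for falls), 0 remained with an estimated correlation, 40 remained with median centring, 39 with scaling on the external control spots and 52 without the dye term. The sign of the median, or camera's direction where so named, turned for called lists as follows. Camera's direction, which is relative to all other genes, was reversed for 2 list calls with median centring and for 1 with scaling on the external control spots. With median centring the median depletion effects at 10 min of the translation factor, proteasome and ribosome biogenesis lists became 0.026, 0.019 and 0.0070, and the cause was not tested. Scaling on the external control spots moved the median of all genes by 0.533 at 20 min and 0.265 at 30 min, and it also leaves out loess, so turns under it combine both changes. Ribosomal protein genes at 30 min stood at -0.31 with median centring and at 0.03 on this scale. This scale turned the medians of all 14 list calls for falls to between 0.026 and 0.562, with 0.554 for the proteasome list at 10 min. The median of all genes was itself 0.54, 0.54 and 0.27 at 10, 20 and 30 min on this scale. A positive list median there is therefore not by itself a turn relative to other genes. The median of the drug efflux list at 10 min turned negative without Mot1-aa 10 min culture 2. For the respiratory chain list at 10 min, camera's direction turned to a fall without Mot1-aa 10 min culture 1 (median 0.0222, adjusted p = 0.995) and stayed a rise without culture 2 (median 0.255), for a cause not tested. At 20 min scaling on the external control spots turned GDS1 to 0.017, UTP14 to 0.092, RPS23B to 0.093, SOF1 to 0.094 and HFI1 to 0.17, all still below the median of all genes on that scale, 0.54. The planned comparison of genes with and without a promoter TATA box, with its alternatives, was not run, because no genome sequence was at hand.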

Other observations

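The lists in this part and their tests were planned. The single genes MF(ALPHA)2, THR1, STR3, CYS3, SCJ1 and NCB2 were chosen after their values were seen. Several metabolic lists had members that passed at 30 min without the list being called. Over all genes the share that passed in either direction was 21.07%. It was lower in the phosphate (15.38%), glucose-repressed (16.67%) and galactose (12.5%) lists, whose passing members therefore do not set them apart on that share. Their passing members were all rises, and shares of rises alone were not compared. It was higher in the amino acid (33.33%), methionine (36.36%) and unfolded protein (36.36%) lists. Of 39 amino acid genes of the Gcn4 type 12 rose and 1 fell (12 and 4 adjusted over the list alone; median 0.13, adjusted p = 0.0861; adjusted p = 0.333 with an estimated correlation). ARG3 (YJL088W) rose by 1.25 (SE 0.17), LYS9 (YNR050C) by 0.99 (SE 0.13) and LYS1 (YIR034C) by 0.98 (SE 0.14), while THR1 fell by 0.65. The amino acid list was called at 10 and 20 min (adjusted p = 0.00288 and 0.0011; 0.18 and 0.155 with an estimated correlation), and at 30 min with median centring, with scaling on the external control spots and without the dimmest genes. Of 22 methionine and sulfur genes 6 rose and 2 fell (6 and 3 adjusted over the list alone; median 0.02, or -0.038 with median centring, adjusted p = 0.626). MET3 (YJR010W), MET14 (YKL001C) and MET10 (YFR030W) of sulfate assimilation rose by 1.03, 0.86 and 0.53. STR3 and CYS3 of the cysteine branch fell by 0.58 and fell by 0.46. The methionine list was called at 10 and 20 min (adjusted p = 1.37e-04 and 0.0164; 0.155 and 0.294 with an estimated correlation), though not without WT-aa 0 min culture 1 (0.0662 and 0.182), nor at 20 min with median centring or scaling on the external control spots. At 10 min the amino acid call ended without Mot1-aa 10 min culture 1 or WT-aa 0 min culture 2 (highest adjusted p 0.173). Of 13 phosphate regulon genes PHM8 and PHO8 (YDR481C, 0.77) rose and 11 did not pass (2 adjusted over the list alone; median 0.17, adjusted p = 0.113). Of 18 glucose-repressed carbon genes ALD4 (YOR374W), ACH1 (YBL015W) and ADH2 (YMR303C) rose, by 0.80, 0.74 and 0.41 (3 adjusted over the list alone; median 0.11, or -0.06 with median centring, adjusted p = 0.226). Of 8 galactose genes GCY1 (YOR120W) rose by 0.68 (1 adjusted over the list alone), and the list's median of -0.03 (0.021 with the authors' values) and mean of 0.05 differ in sign (camera direction down, adjusted p = 0.976). Of 11 genes of the unfolded protein response PDI1 (YCL043C), SIL1 (YOL031C) and MPD1 (YOR288C) rose, by 0.61, 0.39 and 0.34, and SCJ1 fell by 0.55 (3 and 1 adjusted over the list alone; median 0.34, adjusted p = 0.161). None of 12 pyrimidine and uracil uptake genes passed, a point of interest because 4tU enters through uracil uptake (0 adjusted over the list alone; median 0.09, adjusted p = 0.406), with URA2 (YJL130C) nearest at 0.37 (adjusted p = 0.0687). PHO8, MET10, ADH2, PDI1, SIL1 and MPD1 missed the threshold without WT-aa 30 min culture 2, and all but MET10 also without Mot1-aa 30 min culture 1 (highest adjusted p 0.0541, 0.054, 0.0697, 0.0815, 0.138 and 0.124). Without the dye term MET10, ADH2, PDI1, SIL1 and MPD1 missed it, with median centring PHO8, MET10, ADH2, SIL1 and MPD1, and with the authors' values MPD1. URA2 passed without either Mot1-aa 10 min array (0.0203), and the phosphate list was called without WT-aa 0 min culture 2 (0.0496).

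Of the cell cycle and cell type lists none was called at 30 min. In each of them and in the COS family the share that passed in either direction was under the 21.07% of all genes. The exceptions were the G1/S list (26.92%) and the 4 alpha-specific genes (50%). Of 26 G1/S genes 7 rose (8 adjusted over the list alone; median 0.16, adjusted p = 0.0722), with PCL1 (YNL289W), CLB6 (YGR109C) and RNR1 (YER070W) at 0.73, 0.69 and 0.64. This list was called at 10 and 20 min (adjusted p = 4.67e-04 and 0.0023; 0.327 and 0.354 with an estimated correlation), at 10 min not without Mot1-aa 10 min culture 2 (0.622). Of 9 G2/M genes CLB1 (YGR108W) rose by 0.60 (1 adjusted over the list alone; median 0.21, adjusted p = 0.377). Of 11 daughter cell separation genes DSE4 (YNR067C) and DSE1 (YER124C) rose by 0.38 and 0.31 (2 adjusted over the list alone; median 0.18, adjusted p = 0.368). None of 10 histone genes passed (0 adjusted over the list alone; median 0.21, adjusted p = 0.189), with HTB2 (YBL002W) at 0.25. Of 19 pheromone response genes PRM1 (YNL279W), FUS3 (YBL016W) and AGA1 (YNR044W) rose, by 0.71, 0.56 and 0.49 (3 adjusted over the list alone; median 0.08, adjusted p = 0.351). Of 20 genes of meiosis and sporulation, which haploid cells keep low, RIM4 (YHL024W), SMK1 (YPR054W) and SPS4 (YOR313C) rose, by 0.82, 0.73 and 0.59 (3 adjusted over the list alone; median 0.13, or -0.11 with median centring, adjusted p = 0.182). None of 7 genes of the other mating type passed (0 adjusted over the list alone; median 0.02, or -0.14 with median centring and -0.013 with the authors' values, adjusted p = 0.933), with STE6 (YKL209C) at 0.17. Of 4 alpha-specific genes, too few for the list test, STE3 (YKL178C) rose by 0.47 and MF(ALPHA)2 fell by 0.75 (1 and 2 adjusted over the list alone). Of 10 genes of the subtelomeric COS family COS111 (YBR203W) rose by 0.96 (1 adjusted over the list alone; median 0.28, adjusted p = 0.103). RNR1, DSE4, DSE1, FUS3, AGA1, STE3 and COS111 missed the threshold without Mot1-aa 0 or 30 min culture 1 or WT-aa 30 min culture 2, among other arrays (highest adjusted p 0.0778, 0.13, 0.158, 0.136, 0.139, 0.087 and 0.067). Without the dye term RNR1, DSE4, DSE1, FUS3, AGA1 and STE3 missed it, with median centring DSE4, DSE1, FUS3, AGA1 and SPS4, and with the authors' values DSE1 and AGA1. DSE1 also missed it without background correction and without the dimmest genes. At 30 min the G1/S list was called without culture 2 of either strain at 0 or 30 min (lowest adjusted p 0.00494) and without the dimmest genes, the histone and meiosis lists without WT-aa 0 min culture 2 (0.0349 and 0.0437) and the COS list without Mot1-aa 0 min culture 2 or WT-aa 30 min culture 1 (0.0386) or with the authors' values. HTB2 passed without either Mot1-aa 10 min array (0.0406).

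Of 4 genes known to need Mot1 in steady-state studies, too few for the list test, BNA1 (YJR025C) fell by 0.52 at 30 min (SE 0.13, adjusted p = 0.0193; 1 adjusted over the list alone) and was already lower in Mot1-aa at 0 min, at -0.44 (SE 0.09, adjusted p = 0.0329). BNA1 missed the threshold at 30 min without culture 1 of Mot1-aa or culture 2 of WT-aa at 0 or 30 min (highest adjusted p 0.0891), or with median centring. URA1, GAL1 and GAL10 stood at 0.04, -0.22 and -0.16 and did not pass. Cells grew in 2% glucose, so GAL1 and GAL10 were not measured under induction by galactose. The median of the 4 genes was -0.19, or -0.50 with median centring. GAL1 and GAL10 are also in the galactose list and URA1 in the pyrimidine list. NCB2, a subunit of the NC2 complex that also acts on the TATA-binding protein, was higher in Mot1-aa at 0 min by 0.59 (SE 0.09, adjusted p = 0.00618).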
